A study of Homo sapiens with 6 samples.

How the data were processed

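GR binding was measured by ChIP-seq in a GR cell line and an MR/GR cell line, both derived from U-2OS, after vehicle or dexamethasone. Of the 6 samples, 4 were GR immunoprecipitations, each with 3 peak lists, and 2 were input DNA, for which no peak list was used here. The labels give dexamethasone as the treatment of the GR-cell input and vehicle as that of the MR/GR-cell input. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and size-selected libraries were amplified by PCR.

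The deposited lists hold a chromosome, a start and an end per peak, and no score, height, fold enrichment or p-value. Per the submitters' processing notes, the hg19 build, Trim Galore 0.4, Bowtie, SAMtools 1.3.1, Picard 1.115 and HOMER 4.8.3 were used, with the role and settings of each not given in the sources used here. The names of the deposited lists mark each as set against input. Which input served which list, and the calling threshold, are likewise not given in the sources used here. The authors deposited 3 lists per immunoprecipitation, so lists were compared as called one by one and were taken as replicates (n = 3). List numbers come from the deposited lists and not from the labels. Each list has a typical peak width of its own, between 280 and 424 bp over the 12 lists, and the treated lists were 354 to 424 bp wide in the GR cell and 280 to 304 bp in the MR/GR cell. Wider peaks overlap more easily, which is why peak centres were also used as an alternative. Read depth is unknown, so a peak that is not listed may be absent or may lie under the calling threshold. PCR duplicates and depth could change the number of peaks called from equal binding. Peaks on sequences other than the numbered chromosomes, X and Y totalled 97, or 0.0834% of 116356.

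Peaks per list were compared as log2(peaks + 1) by exact permutation tests, two-sided, with 20 arrangements for 3 lists against 3 and 400 for tests stratified by line or treatment. Sites were regions merged from overlapping peaks (at least 1 bp) of all 6 dexamethasone lists, and a site was held by a line when at least 2 of its 3 lists had a peak there. Shares of sites have Wilson 95% intervals, which cover counting error only. Overlap expected by position alone came from 100 seeded random placements. These were uniform over the span of each chromosome and ignored where peaks can be called, so they set a low baseline. Shares of peaks per chromosome were computed for 23 chromosomes, with Benjamini-Hochberg adjustment. Odds ratios have 95% intervals from the normal approximation to the log odds ratio. Permutation tests over windows of 10 Mb (with at least 20 sites each) and over chromosomes used 100000 resamples, and the correlation of neighbouring windows used 10000. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used, and merged sites were checked against bedtools 2.31.1. The site calls were tested on simulated data for the comparison of the treated lines, with 20180 simulated sites. The total recovered, and the totals of shared and one-line sites, were each 100% of the simulated totals, and single sites were not checked. Simulated sites lay farther apart than the closest peaks of the real lists, so crowded sites were not tested.

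Groups, the tests of the planned comparisons, their alternatives and the rule for named sites were fixed before the data were examined, and the closing section names the tests and alternatives chosen later. That rule took, without scores and without an annotation of the build, at most 5 sites per class by coordinates, ranked by the number of peaks within 10 kb over all dexamethasone lists. The classes were sites in 3 of 3 lists of each line, sites in 3 of 3 lists of one line and none of the other, and vehicle sites in at least 2 of 3 lists. The plan had allowed for peak scores, and since the deposited lists carry none, peak strength within a list, fixed score thresholds and lists cut to equal numbers of best peaks were not analysed here. Promoter shares, receptor motifs and genes of fixed lists near sites were not analysed here either, since a genome sequence and gene annotation of hg19 were not used here and the gene table at hand belongs to another build. Alternatives were other overlap criteria, other numbers of lists per site, merged neighbouring peaks, the main chromosomes alone, a pseudocount of 0.5, the list number as a block, and leaving out each list in turn.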

Results

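Glucocorticoid receptor (GR) binding to the genome was mapped by ChIP-seq in a pair of stable human cell lines made from U-2OS, an osteosarcoma line. In one line, named the GR cell, GR was studied alone, and in the other, named the MR/GR cell, the mineralocorticoid receptor (MR) was expressed together with GR. MR and GR are related steroid hormone receptors that act as ligand-activated transcription factors. Cells received vehicle (DMSO) or dexamethasone, a synthetic glucocorticoid, at 100 nM for 2 hr, and chromatin was immunoprecipitated with an antibody against GR. Each of the 4 combinations of line and treatment had 3 numbered peak lists, 12 lists with 116356 peaks in all. The lists give positions without heights or scores, so binding is described by where peaks were called, and the sequencing depth behind each list is unknown. The labels do not say whether the 3 lists of a combination came from separate cultures, so p-values measure only the spread between lists, which may be technical. Each receptor combination was represented by 1 cell line.

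The first question was how far dexamethasone changed the number of GR binding sites in each line. In the GR cell, peaks rose from 196 ± 64.3 per list with vehicle to 31584 ± 5759 with dexamethasone (mean ± SD, n = 3 lists each). In the MR/GR cell, they rose from 61.0 ± 63.2 to 6944 ± 3382 (n = 3 lists each). Peaks covered 11.9 ± 1.23 Mb of the genome in the treated GR cell and 2.01 ± 0.965 Mb in the treated MR/GR cell. On the log2(peaks + 1) scale the dexamethasone response was 7.37 (SE 0.34) in the GR cell, a 165-fold difference, and 7.31 (SE 1.09) in the MR/GR cell, a 158-fold difference. The latter was 8.17 without MR/GR vehicle list 1, the longest of its 3 lists, and 6.43 without list 2, the shortest. Within each line every treated list was longer than every vehicle list, and the exact permutation test gave p = 0.1 (two-sided), the smallest value that 3 lists against 3 allow. Over both lines, with treatments permuted within each line, the response was 7.34 (SE 0.57, exact permutation p = 0.005, two-sided), the smallest p that the 400 arrangements allow.

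The size of the response on this scale was not detectably different between the lines. The difference between the responses was -0.07 on the log2 scale (SE 1.14, exact permutation p = 0.975, two-sided), an error wide enough to leave several-fold differences open. Its sign changed when list 1 of any one combination was left out, to 0.24 for the GR cell with vehicle, 0.07 for the GR cell with dexamethasone, 0.80 for the MR/GR cell with vehicle and 0.32 for the MR/GR cell with dexamethasone. The vehicle lists of the MR/GR cell held between 11 and 132 peaks, a 12-fold range.

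**Figure D1:**
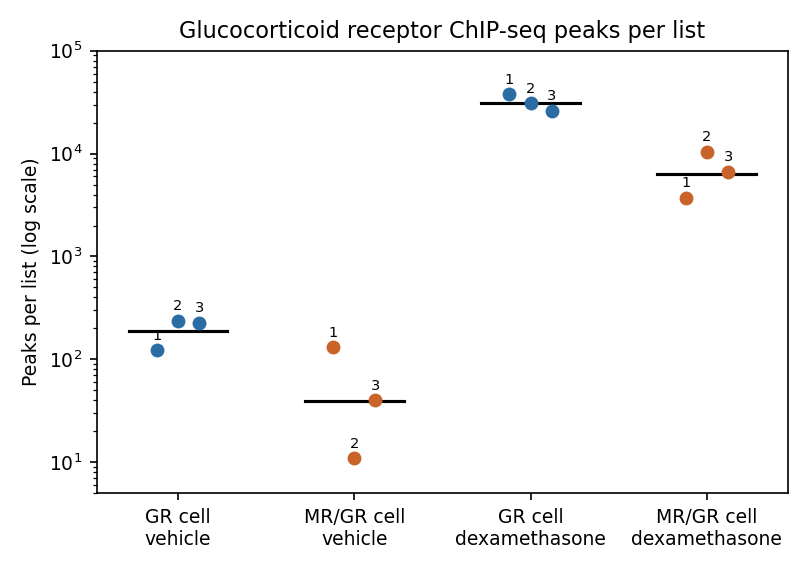
Number of GR ChIP-seq peaks in each of the 12 peak lists (log10 axis), by cell line and treatment. Points are single lists with their list numbers and bars are geometric means; the treated GR-cell lists lie between 26191 and 37650 peaks and the treated MR/GR-cell lists between 3713 and 10459.

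The comparison named by the study's title was between the lines after dexamethasone. The MR/GR cell had fewer GR peaks in each of its 3 lists (3713, 10459 and 6660) than the GR cell had in any of its own (37650, 30912 and 26191). The difference was -2.29 on the log2 scale (SE 0.46), or 4.90-fold fewer peaks, with p = 0.1 in the two-sided exact permutation test, again the smallest possible. With vehicle the difference was -2.23 (SE 1.05, exact permutation p = 0.2, two-sided), and there the lists of the lines overlapped in length. It was -3.09 without MR/GR vehicle list 1 and -1.35 without list 2. Over both treatments, with lines permuted within each treatment, the MR/GR cell had 4.79-fold fewer peaks, a log2 difference of -2.26 (SE 0.57, exact permutation p = 0.01, two-sided).

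Most places bound in the MR/GR cell were also bound in the GR cell. Merging overlapping peaks of the 6 treated lists gave 43713 sites. Of these, 30365 were held by at least 2 of 3 GR-cell lists and 5965 by at least 2 of 3 MR/GR-cell lists, a 5.09-fold difference, and 5425 were held by both lines. Sites of the GR cell therefore contained 90.9% of the MR/GR-cell sites (Wilson 95% interval 90.2 to 91.6), against 0.954% ± 0.116 (SD) for 100 uniform random placements of the MR/GR-cell sites, a low baseline. In the other direction, 17.9% of GR-cell sites were held by the MR/GR cell (17.4 to 18.3). Its ceiling was set by the number of MR/GR-cell sites, 5965 against 30365, so the share mostly repeats the difference in site number. With a site required in both remaining lists, this share was 10.5% without MR/GR list 2, 10.9% without list 3 and 17.0% without list 1, the shortest. List by list, 93.2%, 73.8% and 89.5% of MR/GR-cell peaks lay at GR-cell sites. In turn, 14.8%, 17.3% and 20.2% of GR-cell peaks lay at MR/GR-cell sites, shares that are capped in the same way. These intervals cover counting error over sites only.

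The centres of shared peaks lay close together. The median offset between paired peaks was 26 to 33 bp between the lines, 26 to 29 bp among GR-cell lists and 30 to 33 bp among MR/GR-cell lists. Of the sites in the shorter list of a pair, 91.6% ± 2.51 were found in the longer list within the GR cell (SD over 3 pairs), 89.1% ± 4.44 within the MR/GR cell (3 pairs) and 85.3% ± 9.08 between the lines (9 pairs). The lower value between the lines came from MR/GR list 2, with 71.0% to 79.1%. With MR/GR list 1 or 3 the range was 86.7% to 95.04%, against 84.6% to 94.5% for pairs within either line. List 2 was never the shorter list within the MR/GR cell, so peaks found only in it lowered only the value between the lines. Averaged over both directions of each pair, lists of the same line shared 74.6% of their sites and lists of different lines 51.9%, a measure that falls with any difference in list length and so repeats the difference in peak number. The difference of 22.7 percentage points was the highest of the 10 ways to split the 6 lists into 3 and 3 (one-sided exact permutation p = 0.1, the smallest possible), and the next highest split gave -1.40.

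Sites called reproducibly in one line and never in the other were almost entirely sites of the GR cell. There were 15056 sites in 3 of 3 GR-cell lists and in no MR/GR-cell list, 65.6% of the 22935 sites in all 3 GR-cell lists. The reverse held for 63 sites, 1.95% of the 3228 sites in all 3 MR/GR-cell lists. Both counts follow list length in part, since treated lists held 26191 to 37650 peaks in the GR cell and 3713 to 10459 in the MR/GR cell. The count of 63 depended on the lists used: it was 294 without MR/GR list 1, 106 without GR-cell list 1 and 95 without MR/GR list 3. Among the sites in all 3 MR/GR-cell lists, 96.4% were GR-cell sites.

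Sites found in more GR-cell lists were also found more often in the MR/GR cell. At least 2 MR/GR-cell lists held 1.86% of the sites of 1 GR-cell list (206 of 11088, Wilson 95% interval 1.62 to 2.13), 3.47% of those of 2 lists (258 of 7430, 3.08 to 3.91) and 22.5% of those of 3 lists (5167 of 22935, 21.99 to 23.07). The order was the same in each MR/GR-cell list, with 0.776%, 1.76% and 14.5% in list 1, 6.33%, 8.44% and 30.9% in list 2, and 2.27%, 4.23% and 24.6% in list 3.

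**Figure D2:**
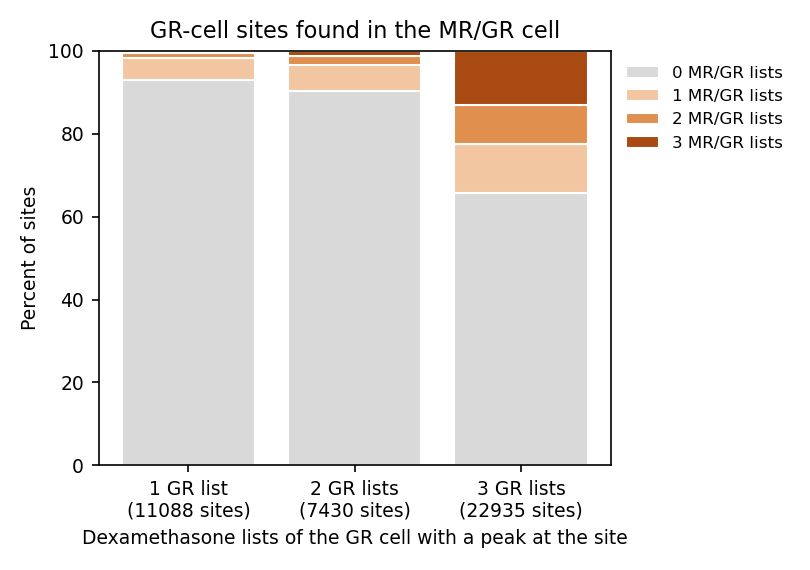
Percent of GR-cell dexamethasone sites found in 0, 1, 2 or 3 MR/GR-cell dexamethasone lists (stacked bars, y axis from 0 to 100%), by the number of GR-cell lists with a peak at the site (x axis). Of sites in 3 GR-cell lists, 65.6% were in no MR/GR-cell list and 13.2% were in all 3.

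Sites were ranked by treated peaks within 10 kb, a count over both lines that favours sites bound in both. Among sites in 3 of 3 lists of a line, a pair of sites on chromosome 11 (114033539 to 114033962 and 114034620 to 114035056, hg19 coordinates counted from 1) and a site on chromosome 6 (35690222 to 35690648) each had 30 such peaks over the 6 lists and were called in all 6. Among sites in 3 of 3 lists of both lines, they were followed by chromosome 10, 74008513 to 74008941, with 27 peaks, and chromosome 11, 114025142 to 114025566, with 26. Among sites in 3 GR-cell lists and no MR/GR-cell list, chromosome 5, 66554348 to 66554771, ranked first with 27 peaks within 10 kb. It was followed by chromosome 20, 46336984 to 46337412 (20 peaks), chromosome X, 106926315 to 106926793 (20 peaks), chromosome 12, 66033503 to 66033938 (19 peaks), and chromosome 18, 56121231 to 56121657 (19 peaks). In the other direction, chromosome 3, 44934181 to 44934564, ranked first with 17 peaks and chromosome 5, 148356391 to 148356712, had 13. Chromosome 10, 30236536 to 30236860, and chromosome 22, 27635134 to 27635440 and 27848979 to 27849317, each had 12. No gene is given for any site, since no gene annotation of hg19 was used here.

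The called peaks of the lines were spread differently over the chromosomes, and chromosome X stood furthest apart. It carried 2.99% ± 0.0880 of treated peaks in the GR cell and 1.34% ± 0.173 in the MR/GR cell (SD, n = 3 lists each), a ratio of 0.448. Chromosome 13 also had a lower share in the MR/GR cell (1.503% ± 0.277 against 2.30% ± 0.103), while chromosome 20 (3.69% ± 0.700 against 2.75% ± 0.0575) and chromosome 22 (2.43% ± 0.120 against 1.84% ± 0.0324) had higher shares. The shares of the 3 lists per line did not overlap on 16 of 23 chromosomes, 7 higher and 9 lower in the MR/GR cell, where chance gives 10% or 2.3 chromosomes. The shares of a list depend on one another, so the 16 are not independent results. The lines also differed in list length, which may affect the shares. For a single chromosome the exact permutation test cannot give less than p = 0.1 (two-sided), and the smallest value was 0.144 after Benjamini-Hochberg adjustment over 23 chromosomes.

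The same chromosomes stood apart in the fraction of sites of 3 GR-cell lists that at least 2 MR/GR-cell lists held. This fraction comes from the same 6 lists and largely restates the chromosome shares, so it is not separate evidence. On chromosome X 12.1% of such sites were held (80 of 659, Wilson 95% interval 9.86 to 14.9), against 22.8% on the autosomes. Chromosome 13 was lowest among autosomes at 15.2% (80 of 528, 12.3 to 18.5) and chromosome 22 highest at 29.2% (25.1 to 33.6), with chromosome 20 at 27.2% (23.9 to 30.8). Chromosome X ranked lowest of 23 in each MR/GR-cell list, at 5.92%, 17.5% and 13.5%.

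**Figure D3:**
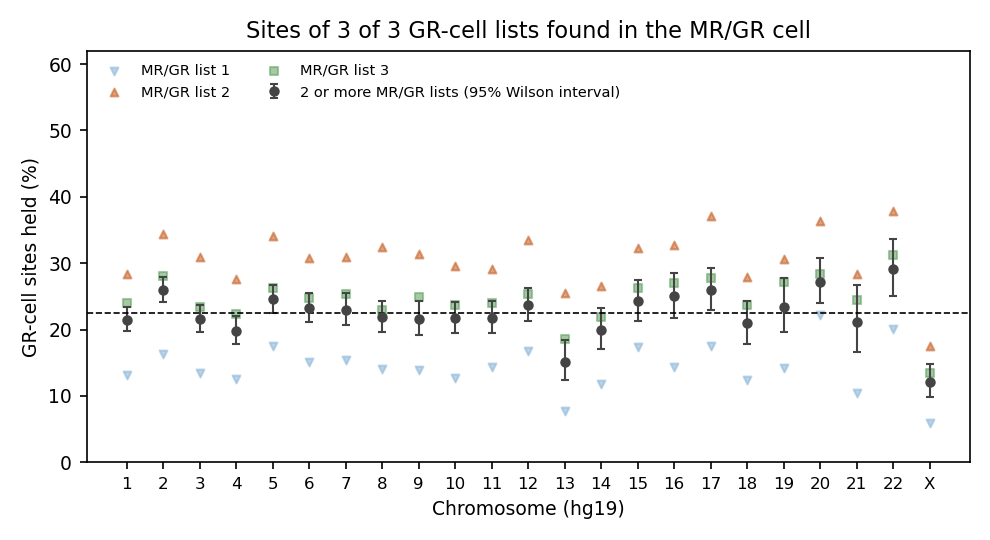
Percent of sites in 3 of 3 GR-cell dexamethasone lists that were found in the MR/GR cell (y axis), by hg19 chromosome (x axis). Black points are sites in at least 2 MR/GR-cell lists with Wilson 95% intervals, coloured points are single MR/GR-cell lists, and the dashed line is the value over all chromosomes, 22.5%; chromosome X lies lowest at 12.1%.

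The few peaks called without ligand were compared with the sites bound after dexamethasone. In the GR cell, 55.7% ± 5.06 of vehicle peaks lay at dexamethasone sites of the same line (SD, n = 3 lists; 61.5%, 52.1% and 53.5%), against at most 0.918% for random placement. In the MR/GR cell the share was 13.7% ± 5.63 (12.1%, 9.09% and 20%), against at most 0.182% for random placement. The difference was -42.0 percentage points (exact permutation p = 0.1, two-sided, the smallest possible), with 30365 sites as the target in the GR cell and 5965 in the MR/GR cell. Against the same MR/GR-cell sites, the shares of GR-cell vehicle peaks were 8.20%, 13.9% and 8.33%, in the range of those of the MR/GR cell or below it. Against the GR-cell sites, the shares of MR/GR-cell vehicle peaks were 29.5%, 9.09% and 32.5%, each below those of the GR cell. The MR/GR-cell share rested on few peaks and few sites: it was 4.37% without MR/GR dexamethasone list 2 or without list 3. With a peak in any treated list of either line as the target, the shares were 77.5% ± 4.17 and 66.3% ± 10.4.

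Vehicle sites found in at least 2 of 3 lists numbered 90 in the GR cell and 20 in the MR/GR cell. Of these, 73 (81.1%) and 8 (40.0%) were dexamethasone sites of the same line. By the same ranking, the leading GR-cell vehicle site was chromosome 6, 35695697 to 35696046, which was also in 3 of 3 treated lists of both lines. The next were chromosome 12, 125399086 to 125399437, chromosome 2, 47403563 to 47403959, chromosome 8, 143751198 to 143751572, and chromosome 16, 89787162 to 89787842. Each was in 3 treated GR-cell lists, and they were in 1, 2, 0 and 1 treated MR/GR-cell lists. In the MR/GR cell the leading vehicle sites were chromosome 19, 4791382 to 4791780, chromosome 3, 119395819 to 119396122, chromosome 17, 72510679 to 72511223, chromosome 22, 35887403 to 35887817, and chromosome 3, 128879908 to 128880215. The site at 119395819 was called in all 3 vehicle lists and all 3 treated lists of both lines. The site on chromosome 22 was in 2 vehicle and 2 treated MR/GR-cell lists and in no GR-cell list. With peak centres at most 100 bp apart as the criterion, a site could split, and only the part in most lists was counted. For the chromosome 19 site that part was in 1 more treated list of the MR/GR cell than of the GR cell. By overlap, the GR cell had 1 more.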

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

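Of 224 alternatives, 195 were counted as kept. For tests this meant the same direction and side of 0.05, for counts a change within a fixed ratio, and for shares a move under their spread. Named sites had to keep their value. Alternatives for the share of GR-cell sites held on chromosome X, for neighbouring sites and for leaving out X were chosen after seeing the data. Exact permutation tests of 3 lists against 3 cannot pass 0.05, so there a large change in size also counted as kept. Stability of those results is therefore read from size and direction. Without MR/GR vehicle list 1 or 2 the MR/GR response was 8.17 or 6.43 and the vehicle difference between lines -3.09 or -1.35. Same-numbered treated lists of the lines had correlations of 0.103, -0.0249 and -0.00675, and differently numbered ones -0.126 to 0.111. The check thus gave no sign that list numbers pair the lines, but it cannot rule pairing out. That check did not cover the vehicle lists. With the list number as a replicate block, the dexamethasone effect over both lines stayed 7.34 and the line effect -2.26 (log2), each with an exact sign-flip p = 0.25 (two-sided), since 3 blocks allow nothing smaller, and no other call changed. Leaving out 1 list moved the difference between the lines' responses from -0.94 to 0.80, with positive values without list 1 of the vehicle GR cell (0.24), treated GR cell (0.07), vehicle MR/GR cell (0.80) or treated MR/GR cell (0.32). With sites in at least 1 list, 80.6% of MR/GR-cell sites were GR-cell sites and 22.6% of GR-cell sites were MR/GR-cell sites; with all 3 lists required the latter was 13.2%. Leaving out 1 list gave 86.7% to 96.1% for the former and 10.5% to 22.01% for the latter, lowest without MR/GR list 2 (10.5%) or 3 (10.9%), when list 1, the shortest, was one of 2 lists required. With 1 list left out, the number of sites of the MR/GR cell alone ranged from 67 to 294, with 294 without MR/GR list 1, 106 without GR-cell list 1 and 95 without MR/GR list 3. Vehicle peaks at dexamethasone sites went from 55.7% to 77.5% (GR cell) and from 13.7% to 66.3% (MR/GR cell) with any treated list as target, and to 39.7% in the GR cell with centres at most 100 bp apart. Leaving out 1 list gave 39.3% to 57.5% and 4.37% to 16.1%, the value of 4.37% without MR/GR dexamethasone list 2 or 3. The share of GR-cell sites held on chromosome X minus autosomes, -10.7 points, went to -15.7 with at least 1 list and -7.77 with all 3 lists. Of 50 alternatives for 25 named sites, 48 kept their value. With centres at most 100 bp apart, the site at 4791382 on chromosome 19 went from 1 to -1 (GR-cell minus MR/GR-cell lists). The site at 143751198 on chromosome 8 went from 3 to 2. Under that criterion only the part of a site in most lists was counted, so these values need not describe the whole site. Alternatives that need peak scores, the promoter, motif and gene-list results, and within-list strength were not run. Unknown depth limits any reading of a peak that was not called.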

Other observations

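The splits of the 6 treated lists for sites of one line alone and the test of vehicle peaks were written before their results were seen; the tests of moved binding, lower sensitivity, chromosome shares, chromosome X and neighbouring sites were chosen after.

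Reproducible GR-cell sites with other GR-cell sites nearby were held more often in the MR/GR cell. The share held was 20.6% for sites with no other site within 10 kb (15856 sites), 25.5% with 1 (5799 sites), 30.8% with 2 (1097 sites) and 40.98% with 3 or more (183 sites, Wilson 95% interval 34.1 to 48.2). A hypothesis is that GR at clustered sites may be less affected by the difference between the lines. Sites with a neighbour were held 5.45 percentage points more often (SD 4.49 over 23 chromosomes, higher in 19 of 23, two-sided sign-flip permutation p = 3e-05). On the odds scale, which does not saturate where most sites are found, the ratio was 1.40 (95% interval 1.32 to 1.499) for the MR/GR cell. For GR-cell lists left out in turn it was 1.38 (1.123 to 1.704), 1.39 (1.24 to 1.57) and 0.974 (0.912 to 1.04), similar in size in 2 of 3 GR-cell lists and not in list 3. The GR-cell values ask whether the left-out list had the sites of the other 2 lists. The MR/GR value asks whether at least 2 of 3 lists had the sites of all 3 GR-cell lists. Neighbours were also counted among different sites, so the sizes are not strictly comparable. Clustered sites could simply have stronger peaks, which lists without scores leave open.

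The smaller number of treated sites in the MR/GR cell was weighed first. In 1 of the 10 splits of the 6 lists, the real one, the sites in all lists of one side and none of the other numbered 15056, and the highest other split gave 184, but 10 splits are too few for a share under 0.05. This count also follows list length, since every other split puts a long GR-cell list on both sides. Binding moved to other places is argued against only for sites called in at least 2 MR/GR-cell lists, of which 9.05% were not GR-cell sites. Another 1926 sites were in 1 MR/GR-cell list and in no GR-cell list. New sites under the calling threshold of the MR/GR lists would be missed, so weaker moved binding stays open. An evenly lower sensitivity of the MR/GR lists, through depth or immunoprecipitation, remains open and may account for much of the difference. Sites of 3 GR-cell lists were held 12.1 times as often as sites of 1 list, as a uniformly raised threshold predicts. Sites in more lists are easier to detect under most causes, so this rise does not single out that one. Lower receptor occupancy in the presence of MR, or a different GR level in a separately made line, predicts the same rise and was not tested. The share held was uneven over chromosomes, from 12.1% on X to 29.2% on chromosome 22, and without scores the peak strength per chromosome is unknown.

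Chromosome X, chosen because it ranked lowest of 23, was weighed next. Chromosome shares lay apart on 16 chromosomes in the real split and on at most 2 in any other (1 of 10 splits reached 16), and 10 splits are too few for a share under 0.05. The real split also differs from the others in list length. Chance among windows is argued against: any of 23 chromosomes lay as far from the rest as X with p = 1e-05 (two-sided permutation over 10 Mb windows taken as exchangeable, the smallest possible). Poorer reproducibility of X sites remains open. The odds ratio of X against autosomes was 0.467 (95% interval 0.369 to 0.591) for the MR/GR cell. For GR-cell lists 1, 2 and 3 left out in turn it was 0.577 (0.392 to 0.851), 0.791 (0.610 to 1.026) and 0.940 (0.787 to 1.124), mean 0.770. The intervals of lists 2 and 3 lay above that of the MR/GR cell, and that of list 1 overlapped it. These ratios are not strictly comparable either, since the GR-cell values rest on 1 left-out list and the MR/GR value on at least 2 of 3 lists. A difference in chromosome copy number between the lines could produce the pattern and also remains open, with neighbouring autosomal windows correlated by 0.10 at 10 Mb (one-sided permutation p = 0.116) and 0.115 at 5 Mb (p = 0.0187), where GR-cell lists left out in turn gave 0.140 (p = 0.00800), 0.0288 (p = 0.183) and 0.0358 (p = 0.210); no biological explanation was tested.

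Extra peaks of MR/GR list 2, the longest of that line, were weighed last. It had 1716 peaks (16.4%) found in no other treated list, against 1.67% and 2.22% in the other MR/GR lists. In GR-cell lists 1, 2 and 3 the share was 19.2%, 7.35% and 3.12%. At a vehicle peak lay 1.98% of these peaks (Wilson 95% interval 1.42 to 2.76) and 1.53% of its other peaks (Fisher's exact p = 0.173, two-sided). Background also present without ligand stays open: the share was not below that of the other peaks, and the vehicle lists, with 771 peaks in all, could have held at most 44.9% of the lone peaks. A greater depth of that list could produce such peaks and was not tested.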
